A study of Mus musculus with 4 samples.

How the data were processed

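Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed in MDER 10T cells, mouse fibroblasts that carry an estrogen-inducible MyoD1 according to the series title. Separate libraries were made with antibodies against H3K4me3, H3K27me3 and H3K9me3, and 1 library of whole-cell extract (WCE), sequenced without immunoprecipitation, serves as the control. Each of the 4 groups holds 1 library, so no replicate spread can be measured, and every test on reads compares a mark library with the WCE library and not conditions. Per the labels' protocols, cells grew in DMEM/F12 lacking phenol red with 10% FCS, chromatin was sonicated to a mean of 500 bp, libraries had 18 cycles of ligation-mediated PCR, and bands of 150 to 350 bp were cut from a gel, which hold inserts of 50 to 200 nt. No estrogen treatment is named in the labels.

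The deposited files list signed read positions, with a minus sign for the reverse strand, and hold no peaks and no counts per region. Reads were aligned to the mm8 mouse genome with Bowtie, per the file headers, which give the options e 70, k 2, m 2, n 2 and l 36, and Bowtie is also named in the submitters' processing notes. With these options a read that matches more than 2 places is dropped, so highly repeated sequence is not measured. The deposited lists keep reads with 1 reported position apart from reads with 2, which are listed at both. Positions repeat in the lists, so amplified copies were not removed before deposit. All coordinates below are mm8, counted from 1. The only gene table at hand is for GRCm38.p6, another build, so no position was assigned to a gene. The promoter counts, the profile around transcription starts and the gene lists planned for this series were therefore not run, and regions are named by position.

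Reads with 1 position numbered 2335857 to 3339861 per library. They were collapsed to 1 read per chromosome, position and strand, and each was moved 60 bp along its strand. Chromosomes 1 to 19, X and Y were tiled in 4 kb windows, and mitochondrial reads were left out of the windows. In each window that held at least 1 read of the mark or WCE, a one-sided exact binomial test compared the mark library with WCE, with the expected share set by the autosomal totals of the 2 libraries. A window was called at a Benjamini-Hochberg adjusted p under 0.05 and a depth-scaled ratio of at least 2. Adjoining called windows were joined into stretches. Ratios are mark over WCE after scaling to equal autosomal totals, with 95% exact (Clopper-Pearson) intervals. Intervals cover counting error only, since PCR reads without molecular identifiers are not independent molecules. Where WCE had 0 reads, the ratio was computed against a floor of 3 reads and is given as a lower bound, which leaves out the counting error of the mark reads.

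The calling procedure was tested on simulated libraries with 200 changed windows, drawn from windows not called in the data that held at least 3 WCE reads. Recovery in windows with fewer WCE reads was not simulated. At a 3-fold change it recovered 0% of them for H3K4me3, 1.5% for H3K27me3 and 0% for H3K9me3. At 5-fold it recovered 29.5%, 32.5% and 33.0%, and at 10-fold 83.0%, 87.5% and 85.0%, with at most 1 unchanged window called. In these simulations, with a median of 4 WCE reads per real window, changes of 5-fold or less were mostly missed. The Benjamini-Hochberg threshold depends on how many windows differ, so recovery may be higher in a library with more enriched windows.

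Overlaps of called windows were set against the overlap of independent lists, against lists matched on chromosome and WCE count, and against 20 simulated pairs of unchanged marks that share WCE. They were also recomputed with each mark tested against a different random part of the WCE reads. Calls per 1 Mb region were compared between marks at equal numbers of calls. Distances between stretches were compared with 100 circular shifts along each chromosome. Regions of 1 Mb were compared where WCE had at least 500 reads, and correlated over autosomal regions with at least 100. The named windows are the 10 of each mark with the highest log2 ratio (1 read added) among called windows with at least 20 mark reads, by a rule fixed before the data were examined. Window overlaps were planned then too, while stretches, 1 Mb regions and neighbour distances were chosen afterwards. Alternatives changed the treatment of repeated reads, window size, scaling, thresholds, read shift and the control. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.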

Results

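The data describe where 3 histone methylation marks lie in the genome of MDER 10T mouse fibroblasts. H3K4me3 is typical of active promoters, H3K27me3 of genes silenced by Polycomb, and H3K9me3 of heterochromatin. After removal of repeated positions, the autosomes held 3086567 H3K4me3 reads, 2933567 H3K27me3 reads, 2101444 H3K9me3 reads and 2977697 WCE reads. Repeated positions made up 5.92%, 6.86%, 8.40% and 6.38% of the reads with 1 position. The mitochondrial genome took 3217 WCE reads but 55 H3K4me3, 139 H3K27me3 and 79 H3K9me3 reads.

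H3K4me3 was concentrated in short, strongly enriched regions. Of 580320 windows tested, 13541 were called, which cover 54.2 Mb and hold 42.5% (95% interval 42.4 to 42.5%) of the H3K4me3 reads against 6.34% of the WCE reads. The pooled ratio was 6.67 (6.64 to 6.70). Of 10759 stretches, 78.0% were a single window, and 26.1% of 1 Mb regions held none. The longest ran for 44 kb on chromosome 11 (96128001 to 96172000), with 1345 H3K4me3 and 200 WCE reads (ratio 6.49, 5.59 to 7.56). Long stretches also lay on chromosome 8 from 87656001 to 87692000 (36 kb, ratio 5.03) and from 87852001 to 87884000 (32 kb, 6.16), on chromosome 6 from 52088001 to 52116000 (28 kb, 6.82) and on chromosome 2 from 74524001 to 74548000 (24 kb, 7.75).

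Among the named H3K4me3 windows, the one starting at 18336001 on chromosome 16 held 121 H3K4me3 and 2 WCE reads (ratio 58.4, 15.8 to 487). The window at 73096001 on chromosome 13 held 211 and 5 (40.7, 17.2 to 127), and that at 50260001 on chromosome 12 held 262 and 8 (31.6, 15.8 to 74.0). At 45944001 on chromosome 12, 38 H3K4me3 reads faced 0 WCE reads, at least 12.2-fold higher against the floor of 3 WCE reads, with an exact lower limit of 9.46 once counting error in both libraries is included. The megabase with the most called H3K4me3 windows, 59, was chromosome 10 from 79000001 to 80000000. The highest ratio over a megabase was 2.85 (2.75 to 2.96), on chromosome 19 from 5000001 to 6000000. H3K4me3 calls numbered 20662 with 1 kb windows, each of which covers less of the genome, and 27007 with a uniform background in place of WCE.

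H3K27me3 formed fewer windows called against WCE, which were more unevenly spread over the genome and included some longer stretches. Of 585722 windows, 3654 were called (14.6 Mb), with 4.61% (4.59 to 4.63%) of the H3K27me3 reads against 0.892% of WCE reads and a pooled ratio of 5.14 (5.07 to 5.21). Most stretches were as short as those of H3K4me3, with 78.4% of 2709 a single window and a mean length of 5.40 kb, against 5.03 kb for H3K4me3. Stretches of at least 3 windows held 19.3% of called H3K27me3 windows and 7.62% of called H3K4me3 windows. No H3K27me3 window was called in 66.9% of the 1 Mb regions, and 5% of regions held 47.7% of the calls. In 100 random draws of 3654 H3K4me3 calls, a mean of 47.1% of regions were empty (45.5 to 49.0%) and 5% of regions held 29.2% of the calls (28.0 to 30.5%). At 40 kb from called windows towards lower coordinates, mean H3K27me3 density was 4.96 reads per 1000000, where WCE was at 2.88. Other called windows may lie at that distance, so this does not show a raised level away from all calls.

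The longest H3K27me3 stretch covered 72 kb of chromosome 15 (102736001 to 102808000), with 1137 H3K27me3 and 145 WCE reads (ratio 7.96, 6.69 to 9.53). Others lay on chromosome 8 from 125556001 to 125612000 (56 kb, 4.06), on chromosome 11 from 95980001 to 96024000 (44 kb, 6.10) and from 96064001 to 96104000 (40 kb, 7.38), and on chromosome 6 from 83652001 to 83692000 (40 kb, 6.38). The densest megabases were chromosome 8 from 123000001 (41 called windows), chromosome 11 from 96000001 (36) and chromosome 19 from 44000001 (36). Among the named windows, chromosome 19 at 44804001 held 83 H3K27me3 and 4 WCE reads (ratio 21.1, 7.92 to 79.1), chromosome 10 at 79904001 held 75 and 3 (25.4, 8.36 to 126), and chromosome 11 at 100496001 held 23 and 0, at least 7.78-fold higher against the floor, with an exact lower limit of 5.83. The count depended strongly on the procedure, from 764 windows at 1 kb to 47110 against a uniform background, where it exceeded the 27007 of H3K4me3. The share of H3K27me3 reads in called windows moved with it, to 3.07% at an adjusted p under 0.01, 9.10% with scaling by 100 kb bins and 30.1% against a uniform background. The window count was 1869 where WCE was replaced by the larger of the window and its local mean, an alternative chosen after the data were seen.

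Long stretches of both marks lay in the same neighbourhood on chromosomes 11 and 6. On chromosome 11, the H3K27me3 stretches from 95980001 to 96024000 and from 96064001 to 96104000 lay on the lower-coordinate side of the 44 kb H3K4me3 stretch, and H3K27me3 windows at 96180001 and 96184001, 8 kb away, on the other side. That stretch had an H3K27me3 ratio of 0.558, and the 44 kb H3K27me3 stretch had an H3K4me3 ratio of 0.592. The nearer, 40 kb H3K27me3 stretch had an H3K4me3 ratio of 2.32, and its windows at 96096001 and 96100001 were called for both marks. On chromosome 6, the 28 kb H3K4me3 stretch, 36 kb from the nearest H3K27me3 stretch, had an H3K27me3 ratio of 0.451, and the H3K27me3 stretch from 52152001 to 52184000 had an H3K27me3 ratio of 7.36 (5.90 to 9.29) and an H3K4me3 ratio of 2.14, with the windows at 52152001 and 52160001 called for both marks. The low ratios of the other mark in these stretches do not by themselves show its loss. WCE reads were denser in called H3K4me3 windows, at 1.84 times the density 20 to 40 kb away, which lowers the other ratios there. Scaling by 100 kb bins instead of autosomal totals raised H3K4me3 log2 ratios by 0.82.

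**Figure D1:**
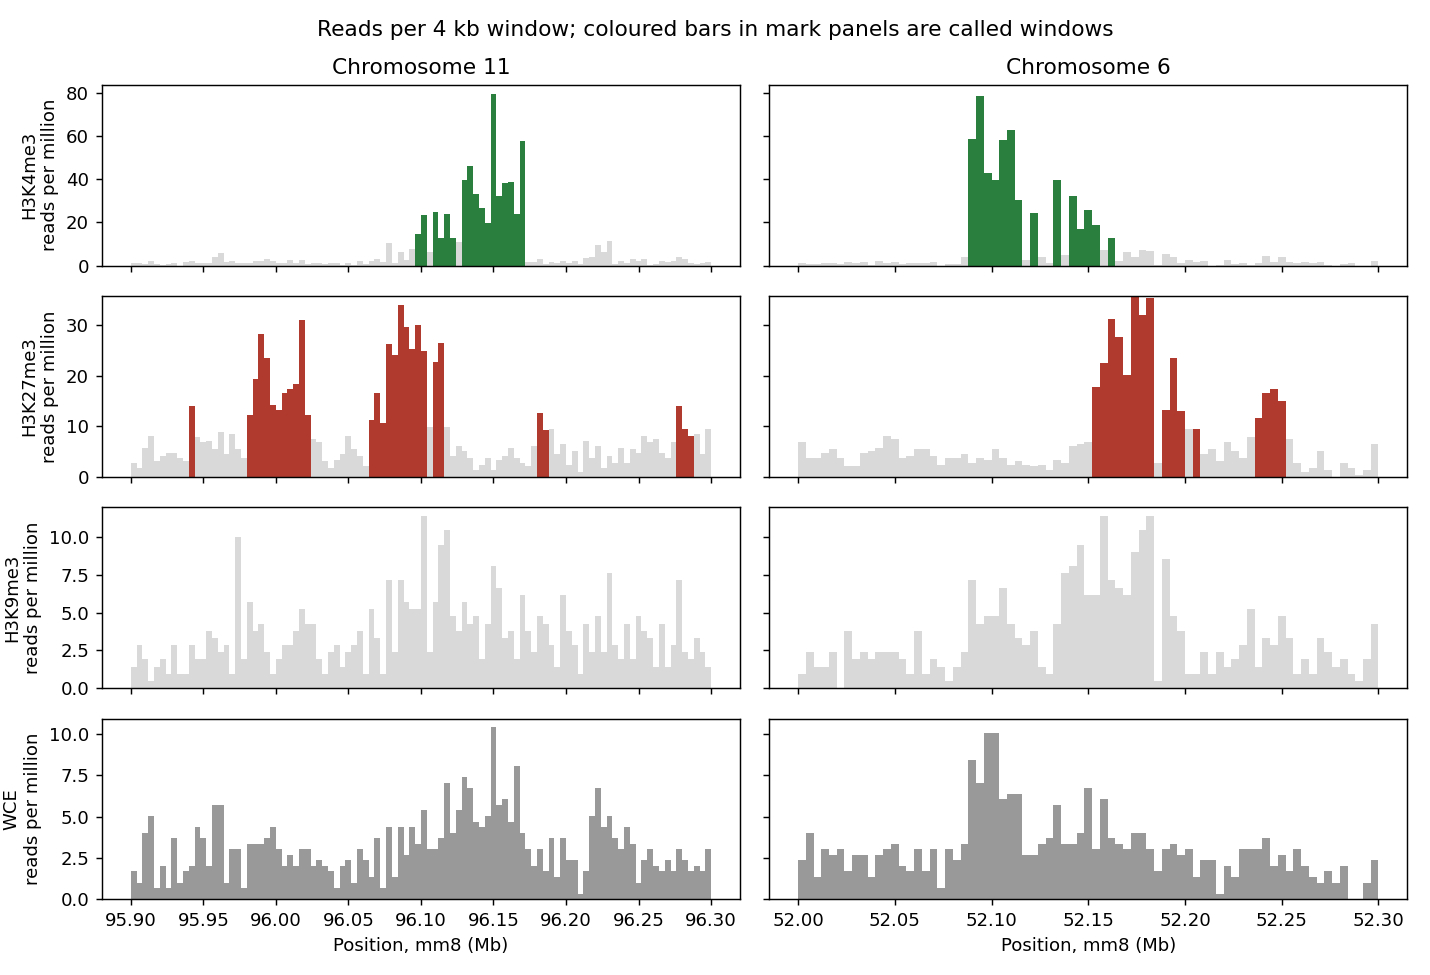
Reads per 1000000 in each 4 kb window (vertical axis) against mm8 position in Mb (horizontal axis) for the 4 libraries on chromosomes 11 and 6. Coloured bars in the mark panels are called windows, and the WCE panel is grey throughout; the H3K4me3 stretch from 96128001 to 96172000 lies to the right of the H3K27me3 stretches between 95980001 and 96104000, with windows called for both marks, for H3K4me3 alone or for neither between 96104001 and 96128000, and H3K27me3 windows at 96180001 and 96184001 lie on its other side.

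Some windows carried both marks. H3K4me3 and H3K27me3 were both called in 295 windows, 8.08% of H3K27me3 windows, where independent lists would share 86.3 and lists matched on chromosome and WCE count 141. Simulated unchanged marks sharing WCE gave 0, but such marks have almost no calls, so this does not measure what the shared WCE adds to the 295. With each mark tested against a different part of the WCE reads, 97 windows were shared, where independent lists would share 22.8. That expectation is not matched on chromosome or WCE count, so it compares with the 86.3 and not with the 141. In the shared windows the median was 48 H3K4me3 reads, against 87 in windows with H3K4me3 alone, and 47 H3K27me3 reads, against 33 in windows with H3K27me3 alone. Examples are chromosome 6 at 30124001 (120 H3K4me3, 138 H3K27me3 and 13 WCE reads), chromosome 6 at 72164001 (123, 81 and 10) and chromosome 3 at 8648001 (62, 55 and 5). An H3K4me3 stretch lay within 20 kb of 31.5% of H3K27me3 stretches (29.7 to 33.3%), against a mean of 18.3% after shifting (15.0 to 21.4% over 100 shifts). Stretches that overlap lie within this distance, so the share is not separate from the windows called for both marks. Shifting keeps neither WCE density nor the presence of both marks in the same megabases, so this excess need not reflect closeness within 20 kb. A window with both marks can come from both on the same chromosomes or from different cells or alleles, which pooled reads do not separate.

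H3K9me3 enrichment was sparse at this scale. Only 114 of 585662 windows were called (0.456 Mb), with 0.221% of the H3K9me3 reads, 0.0479% of the WCE reads and a pooled ratio of 4.60 (4.34 to 4.88). The same windows held 0.0893% of the H3K4me3 reads and 0.0843% of the H3K27me3 reads. Both shares were above that of WCE, so the rise there was not limited to H3K9me3. The longest of 105 stretches covered 16 kb of chromosome 5 (143508001 to 143524000), with 157 H3K9me3 and 33 WCE reads (ratio 6.74, 4.61 to 10.1), followed by 12 kb of chromosome 15 (76000001 to 76012000; 216 and 53 reads, ratio 5.77). Among the named windows, chromosome 12 at 113220001 held 51 H3K9me3 and 5 WCE reads (14.5, 5.81 to 46.4) and chromosome 18 at 37892001 held 45 and 5 (12.8, 5.08 to 41.2). H3K9me3 shared 9 windows with H3K27me3, where independent lists would share 0.722, and lists matched on chromosome and WCE count 0.968. With split WCE, 31 H3K9me3 windows were called and 0 were shared, where independent lists would share 0.0579, too few for a comparison. H3K9me3 shared 12 windows with H3K4me3, where independent lists would share 2.69 and matched lists 12.8. With split WCE 5 were shared, where independent lists would share 0.648. The latter lists were not matched on chromosome or WCE count, and matching had left no excess without the split. The count of called H3K9me3 windows ran from 21 at 1 kb to 19479 against a uniform background, which held 13.3% of the H3K9me3 reads, and at an adjusted p under 0.01 called windows held 0.141%.

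H3K9me3 was also raised over some whole megabases. Of 2239 regions, with a median H3K9me3 ratio of 0.956, 87 were at or below the inverse of 1.5 and 56 had a ratio of at least 1.5. The highest were chromosome 4 from 152000001 (2.25, 2.10 to 2.41) and from 127000001 (2.25, 2.07 to 2.43), chromosome 15 from 87000001 (2.23, 2.08 to 2.38) and chromosome 5 from 113000001 (2.19, 2.04 to 2.35). In these 4 regions the H3K4me3 ratios were 1.09, 0.718, 0.685 and 0.897. Over the 56 regions the H3K4me3 ratio had a median of 0.815 (range 0.501 to 1.42), against 0.855 over all regions, and 34 of 56 (60.7%, 46.8 to 73.5%) lay below the latter. The H3K27me3 ratio had a median of 0.923 (range 0.681 to 1.48), against 0.911 over all regions. None of the 56 reached 1.5 for another mark, but few would be expected to. Over all 2239 regions, 192 reached 1.5 for H3K4me3 and 66 for H3K27me3. The counts also depend on the scaling. With the median ratio over 100 kb bins, 30 of 72 H3K9me3 regions also reached 1.5 for H3K4me3 and 6 for H3K27me3. Over all regions 1129 and 346 then did so, larger shares than among the 72. By autosomal totals, the longest run of H3K9me3 regions at 1.5 or above was 4 Mb, on chromosome 2 from 169000001 to 173000000 (ratio 1.79). Across 2378 regions of 1 Mb, log2 ratios correlated between H3K4me3 and H3K27me3 (Pearson r 0.749 with split WCE), H3K27me3 and H3K9me3 (0.502) and H3K4me3 and H3K9me3 (0.391). Unchanged marks simulated with split WCE gave r between -0.068 and 0.053. With shared WCE, r was 0.762, 0.528 and 0.409, against 0.508, 0.451 and 0.462 for unchanged marks. Regions are not independent replicates. The covariances with shared WCE were 0.256, 0.0700 and 0.0834, against 0.0022 simulated for each pair. These simulations draw unchanged marks around the WCE counts, without any bias that the immunoprecipitated libraries share against WCE. They therefore cannot separate such a bias from marks that vary together.

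**Figure D2:**
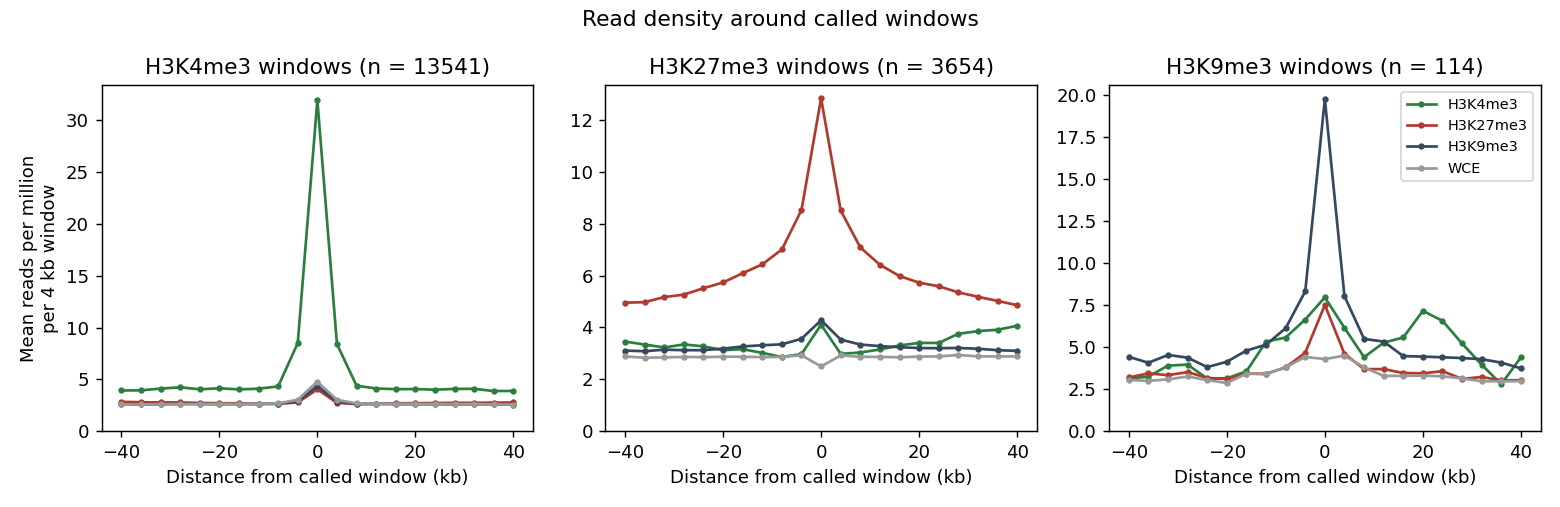
Mean reads per 1000000 per 4 kb window (vertical axis) by distance in kb from called windows of each mark (horizontal axis), 1 line per library. At called H3K4me3 windows H3K4me3 reached 31.9, and at called H3K27me3 windows H3K27me3 reached 12.8 with a gradual decline to 4.96 at 40 kb towards lower coordinates.

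Chromosomes differed in all libraries. WCE reads per Mb ran from 901 on chromosome 3 to 1805 on chromosome 19, and the X chromosome had 397. Relative to WCE and to the autosomal total, H3K4me3 was highest on chromosome 11 (1.24, 1.233 to 1.248) and lowest among autosomes on chromosome 1 (0.868). H3K27me3 was highest on chromosome 11 (1.13) and lowest on chromosome 3 (0.880). The X chromosome was lower for each mark, at 0.805 (0.796 to 0.814) for H3K4me3, 0.761 (0.752 to 0.770) for H3K27me3 and 0.808 (0.798 to 0.818) for H3K9me3. Outside called windows, relative to autosomal reads outside called windows, these were 0.807, 0.782 and 0.808. For H3K27me3 and H3K9me3 nearly all X reads lay outside called windows (48636 of 49222 and 37375 of 37440), so this is no separate check. For H3K4me3, with 32261 of 54824 X reads outside, the lower ratio was not confined to called windows. Called H3K27me3 windows per 1000 numbered 16.4 on chromosome 19 and 14.8 on chromosome 11, but 0.776 on X. Chromosome 11 had 41.0 H3K4me3 windows per 1000 and X 13.1. The lower read density on X lowers the chance of a call there.

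**Figure D3:**
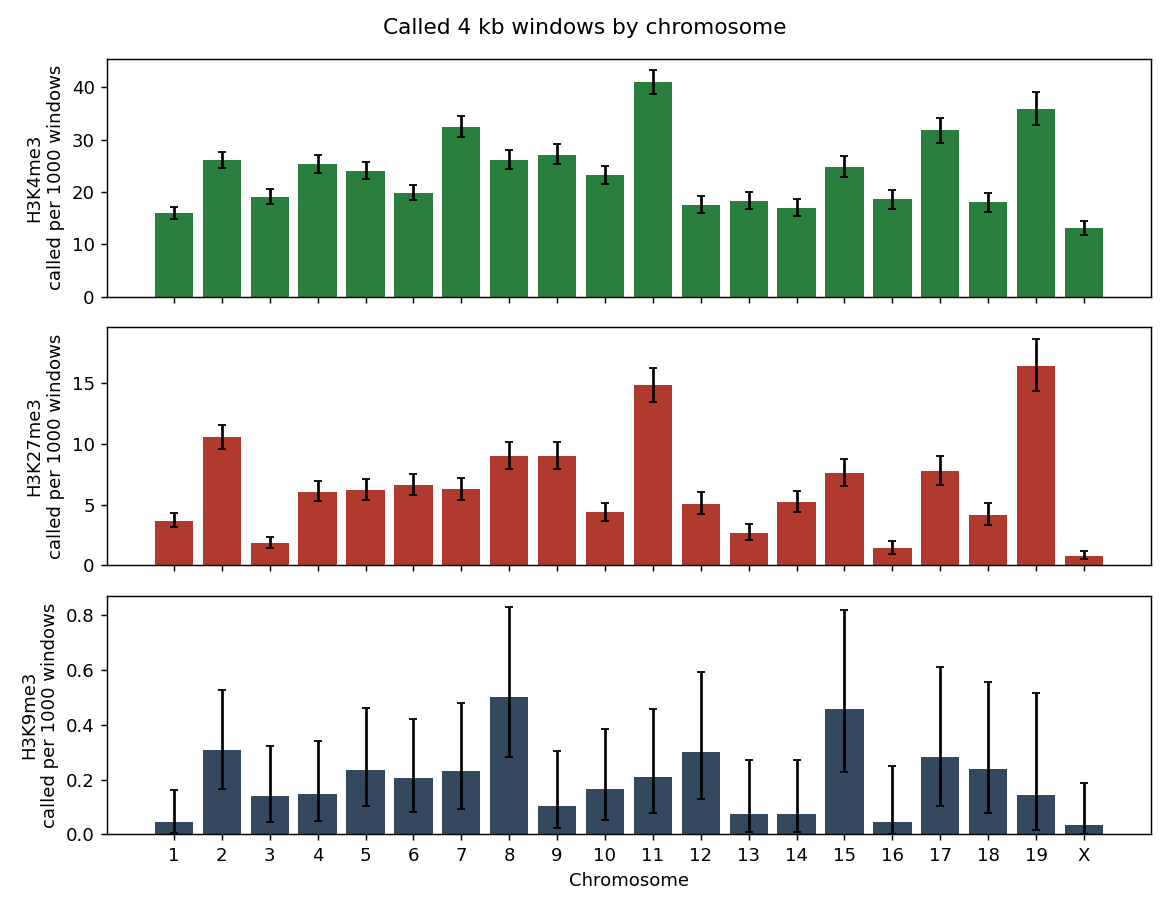
Called 4 kb windows per 1000 windows (vertical axes) on each chromosome (horizontal axis) for the 3 marks, with 95% exact binomial intervals as error bars and Y left out. H3K27me3 reached 16.4 on chromosome 19 and 14.8 on chromosome 11, with 0.776 on X.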

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

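The test of regional copy number and the test of reads with 2 positions were chosen after their results were seen, as were an upper bound on the tests of a fixed share and their repeats in windows called without WCE. Reads with 2 reported positions, outside the window counts above, exceeded WCE in 611 windows for H3K4me3, 37 for H3K27me3 and 16 for H3K9me3. Of the 611, 284 were not called from reads with 1 position. The strongest H3K4me3 cases lay on chromosome 17 between 14696001 and 14732000, where the last window held 453 such H3K4me3 reads and 45 WCE reads. On the same chromosome, the window at 34564001 held 96 H3K9me3, 94 H3K4me3 and 18 WCE reads. On chromosome 11, the window at 52008001 held 97 H3K27me3 and 23 WCE reads. Each such read is listed at both places, so its origin is not known.

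WCE reads were denser in H3K4me3 windows than beside them, at 4.79 reads per 1000000, 1.84 times (95% interval 1.81 to 1.86, from resampled 1 Mb regions) the density 20 to 40 kb away. A regional difference in copy number or mappability would reach the flanks, and this ratio argues against it as the whole cause. A difference in mappability confined to the windows would not reach the flanks, and it was not tested. Reads carried over from the H3K4me3 library would add one fixed share, and the share in the windows with most H3K4me3 reads was 1.08 times (0.992 to 1.19) that in those with fewest. In windows called without WCE the same quantity was 0.122 (0.106 to 0.141), and calling against WCE limits WCE reads in weak windows. Carry-over therefore cannot be told apart from an open-chromatin bias of sonication, or from a difference confined to the windows. The H3K27me3 and H3K9me3 libraries rose there too, 1.47 and 1.68 times, and no biological explanation was tested.

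Few H3K9me3 windows passed the threshold. With H3K27me3 thinned to the H3K9me3 depth, it still had 24.7 called windows for each H3K9me3 window, which argues against depth as the whole cause. Reads with 2 positions were 1.16 times (1.15 to 1.18) as frequent per read with 1 position as in WCE. For H3K4me3 this was 0.831 and for H3K27me3 0.990. The H3K9me3 excess is small, and its bound was set after the result was seen, so it does not decide whether such reads hold much of the mark. Reads with more positions were dropped at alignment and stay untested. Wide regions at low ratios remain open, because the spread of log2 ratios over 100 kb beyond counting error was 0.610 (0.588 to 0.638) of that of H3K27me3, between the bounds set. Antibody efficiency was not tested, and no biological explanation was tested.

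H3K9me3 reads were denser in H3K27me3 windows than beside them, 1.36 times (1.33 to 1.40), where H3K4me3 was at 1.17 and WCE at 0.868 times the flanks. In H3K27me3 windows called without WCE, the WCE ratio to the flanks was 1.20 (1.19 to 1.23) and the H3K9me3 ratio 1.26 (1.24 to 1.29). H3K4me3 rose 1.67 times there and H3K27me3 1.60 times. More fragments of any kind may account for most of the H3K9me3 rise there. The WCE and H3K9me3 intervals do not overlap, but they leave out differences between libraries. The remainder therefore cannot be told apart from a bias that the immunoprecipitated libraries share against WCE. A fixed share of H3K27me3 reads carried over or bound by the H3K9me3 antibody would give a value near 1, and the share in the windows with most H3K27me3 reads was 3.48 times (1.78 to 16.0) that in those with fewest. In windows called without WCE it was 0.763 (0.636 to 0.918), and because selection against WCE reads shapes the former, this cannot be told apart from both marks lying together. The prediction for this test had set no upper bound.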

How the results depend on the processing

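The alternatives with a local WCE mean, thinned libraries, reads with 2 positions added, or chromosome starts and dense WCE windows left out, and all alternatives for shared windows and 1 Mb regions, were chosen after the data were seen. The planned promoter and gene-list alternatives were not run, for want of an mm8 annotation. H3K4me3 gave between 10986 and 19479 windows under 10 of 12 alternatives, against 13541, but 20662 with 1 kb windows and 27007 with a uniform background in place of WCE. H3K27me3 gave 764 windows at 1 kb, 6807 at 10 kb, 9575 with scaling by the median ratio over 100 kb bins, 2032 at an adjusted p under 0.01, 47110 with a uniform background and 1869 with the local WCE mean, against 3654. H3K9me3 gave 21, 407, 52, 19479 and 47 under the same settings except the scaling, where it gave 158, against 114. Windows of 1 kb and 10 kb differ in length from those of 4 kb, so their counts do not compare the length covered. The same holds for shared windows. The uniform background ignores the regional differences in density that WCE shows, and other causes were not tested. Scaling by 100 kb bins raised log2 ratios by 0.82 for H3K4me3, 0.31 for H3K27me3 and 0.08 for H3K9me3, so ratios are relative to that choice.

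Windows shared by H3K4me3 and H3K27me3 numbered 97 at 1 kb, 938 with the 100 kb scaling, 168 at an adjusted p under 0.01, 8874 with a uniform background and 97 with split WCE, against 295. Windows shared by H3K27me3 and H3K9me3 numbered 15 with all reads kept, 1 at 1 kb, 31 at 10 kb, 26 with the scaling, 2 at the stricter p, 8109 with a uniform background, 15 with 2-position reads, 2 with the local mean and 0 with split WCE, against 9. For H3K4me3 and H3K9me3 these were 1 at 1 kb, 30 at 10 kb, 50 with the scaling, 4 at the stricter p, 7490 with a uniform background, 20 with 2-position reads, 7 with the local mean and 5 with split WCE, against 12. Split WCE gives each test fewer control reads. The 1 Mb regions at a ratio of at least 1.5 rose from 192 to 1129 for H3K4me3 and from 66 to 346 for H3K27me3 with the scaling. The cause of the other moves was not tested. X ratios stayed within their intervals with all reads kept. Of the 30 named windows, 28 were called under each of 6 alternatives, and 2 H3K9me3 windows were lost at an adjusted p under 0.01. The 6 were all reads kept, 100 kb scaling, a ratio of at least 3, the stricter p, no shift and a uniform background. The named windows were chosen for high ratios, so the ratio threshold and the scaling could hardly lose them. The other alternatives, among them the local WCE mean, were not applied to them.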

Other observations

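The windows and regions described here were chosen after the data were seen. The 5 windows with most WCE reads lay on chromosome 17 from 39448001 to 39460000 (2021, 568 and 539 reads in single windows), on chromosome 2 at 98464001 (409) and on chromosome 5 at 3000001 (335). H3K4me3 ratios in them ran from 0.473 to 0.608, H3K9me3 ratios from 1.11 to 1.53, and H3K27me3 ratios from 0.506 to 1.36, above 1 in the 3 windows on chromosome 17 only.

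The lowest H3K4me3 megabase was chromosome 15 from 49000001 to 50000000, with a ratio of 0.263 (0.219 to 0.314), an H3K27me3 ratio of 0.554 and an H3K9me3 ratio of 0.720. The lowest for H3K27me3 was chromosome 17 from 60000001 to 61000000 (0.402, 0.353 to 0.458), and for H3K9me3 chromosome 14 from 96000001 to 97000000 (0.517, 0.446 to 0.597). H3K4me3 stretches lay within 20 kb of 38.1% of the 105 H3K9me3 stretches (28.8 to 48.1%), against a mean of 17.2% after shifting (7.62 to 26.7% over 100 shifts). H3K27me3 stretches lay within 20 kb of 14.3% (8.22 to 22.5%), against 5.19% (0 to 11.4%), so the interval and the range of shifts overlap. Stretches that overlap lie within this distance, so neither share is separate from the shared windows. Shifting does not keep WCE density, and for shared windows of H3K4me3 and H3K9me3, matching on chromosome and WCE count left no excess (12 against 12.8).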
